A study of Mus musculus with 20 samples.

How the data were processed

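The study measured mature miRNAs in EVs on 20 arrays, with 3 arrays in each of 4 Abcg2-model groups and 2 in each of 4 NHD13 groups. Per the labels' protocols, marrow cells from C57BL/6 mice were cultured in EV-depleted serum with hematopoietic cytokines for 72 h, EVs were collected by stepwise centrifugation, filtration and ultracentrifugation, and 100 ng of RNA was labelled with Cy3. The arrays are 1-colour Agilent mouse miRNA arrays. The intensity values that were deposited are Agilent Feature Extraction output per spot, including the background-subtracted processed signal, and per the file headers version 11.5.1.1 was used for the 6 unsorted arrays and 12.1.1.1 for the other 14, while the submitters' processing notes name 12.1.1.1 only. The detection, outlier and control flags are other values that Feature Extraction wrote, per the file headers. The log2 values are the authors' deposited series values, whose scaling is stated in none of the sources used here. All 1881 mouse miRNAs were matched by name in that set of 1902 entries, and at least 98.2% of values per array equalled log2 of the total gene signal minus a constant for that array, within 0.01. The column medians were -8.72, -9.13 and -8.47 in unsorted controls, -10.19, -10.21 and -10.04 in unsorted Abcg2, -8.21, -8.48 and -8.19 in cKit+ controls, and -6.35, -5.91 and -7.01 in cKit+ Abcg2. They were -8.29 and -8.11 in WT A1, -8.88 and -9.31 in WT B1, -9.17 and -9.54 in Tg A2, and -8.38 and -9.26 in Tg B2. Scale and direction are thus known, and how each constant was set stays unknown.

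Control spots were left out, and spots flagged as outliers were left out unless all spots of a probe were flagged. Processed signals were averaged over the spots of a probe and then over the probes of a miRNA on the linear scale, giving 1881 miRNAs from 4415 probes, 1493 of them with 2 probes. Each array was divided by the 75th percentile of signal over miRNAs detected on every array of the fit (the scaling signal), floored at the median over arrays of the lowest scaled signal of a detected miRNA, and put on the log2 scale. Detection was the gene-level flag in the files. miRNAs detected on every array of at least 1 group were tested. A miRNA detected on no array of a group has only a bound there: the brighter group's mean against, per array, the higher of the lowest detected scaled signal and its own value. Since an array's lowest detected signal can lie below the floor, the smaller of this fold and the fold of the fit is given, as at least N-fold, a choice made after the values were seen. Values at the floor have no order. miRNA names and mm9 positions are those in the array files; 690 miRNAs have a position and 633 have exactly 1.

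Tests used limma 3.58.1 (lmFit, eBayes) in R 4.3.3 with the packages statmod 1.5.0 and data.table (version 1.17.8), with Benjamini-Hochberg adjustment over tested miRNAs and a threshold of 0.05, and all adjusted p-values are from limma. Plots used matplotlib 3.10.9 in Python 3.11.15. Abcg2 was compared with control in unsorted and in cKit+ EVs, each in a fit of 6 arrays, and the difference of these effects in a fit of 12. NHD13 was compared with wild type in 8 arrays with the set letter as an additive term, and sets A and B and their difference came from a fit with 4 group means. Summed signal and detected miRNAs were compared with two-sided exact permutation tests. The number of arrays limits the precision. On simulated data with 200 changed miRNAs, the fit recovered 85% of changes of log2 size 1 and 99% of size 2 for unsorted EVs (533 miRNAs, 7.54% of calls false), 51% and 99% for cKit+ EVs (431 miRNAs, 2.60% false), and 26% and 91% for NHD13 (590 miRNAs, 2.50% false).

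There were 22 miRNA lists: miR-17-92 and its paralog clusters, let-7, myeloid, erythroid, lymphoid, stem and progenitor, Hox-cluster, NF-kB-induced, miR-15 family (with miR-16 and miR-322), miR-29, miR-30, miR-34, Runx2-targeting, Dlk1-Dio3, mesenchymal and osteolineage stromal, endothelial, epithelial, hepatocyte and serum, neural and muscle markers, GC-rich late-registry miRNAs, and the Sfmbt2 cluster. Some miRNAs are in more than 1 list. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the lists of a comparison. Camera compares a list with the other miRNAs, and fry does not. Named miRNAs are, per comparison, the 10 largest changes per direction among those that passed. Where fewer than 10 passed, they are those and the smallest p-values up to 5, named as not passing. From each tested list the 2 members with the largest moderated statistic are named, with all members of lists of 5 or fewer. The same 10 miRNAs were followed in every comparison (miR-223-3p, miR-142a-3p, miR-21a-5p, miR-146a-5p, miR-155-5p, miR-150-5p, miR-451a, miR-10a-5p, miR-196b-5p and miR-126a-3p), and for a difference of effects the 5 smallest p-values. Other list members given as examples for the NHD13 sets or for larger lists were chosen after their values were seen.

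The groups, tests, lists and this naming rule were chosen before the data were examined, as were most alternatives: normexp background correction (offset 50), the 75th percentile over all mouse miRNAs, quantile normalization, no filter on dim miRNAs, only miRNAs detected on every array, total gene signal, the authors' series values, a doubled floor, all 20 arrays in 1 fit, trended and robust variance, the replicate number as a block, for NHD13 no letter term, averaged arrays or source as a random block, and leaving out each array. Chosen after seeing the data were normexp on the median signal where the files hold no mean signal column (all but the 6 unsorted arrays), a correction of each array for its trend on probe GC content, log2 scaling signal as a covariate, leaving out miRNAs with 1 value on all arrays (with and without the filter), the cKit+ fit without the 2 dimmest Abcg2 arrays, and a crossed replicate block for set B. Slide and scan could not enter as a block, since each comparison lay on 1 slide. Some arrays detected fewer miRNAs than lie above the percentile over all mouse miRNAs, so that this scaling rests on signal near background there. They were all cKit+ arrays, Control unsorted replicates 1 and 3, WT A1 replicates 2 and 3, and Tg B2 replicate 2.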

Results

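Extracellular vesicles (EVs) are membrane-bound particles that cells release and that carry small RNA. Mature miRNAs were measured in EVs that bone marrow cells from control mice, and from mouse models of myelodysplastic syndrome (MDS), shed into culture medium over 72 h. MDS is a clonal disorder of blood-forming cells that can progress to acute myeloid leukemia (AML). The comparisons ask how the miRNA content of EVs differs between diseased and control marrow. In the model the labels name Abcg2 MDS/AML, after a gene for a membrane transporter, 3 arrays held EVs from control cells and 3 held EVs from Abcg2 cells, with no sorting named (unsorted). Another 3 control and 3 Abcg2 arrays held EVs from cells positive for cKit, the stem cell factor receptor carried by blood progenitors (cKit+). The other model was transgenic for NUP98-HOXD13 (NHD13), a leukemia fusion gene, with 4 wild-type and 4 transgenic arrays. These 8 arrays fell into sets A and B, with 2 arrays of each genotype per set, and the labels do not say what the letters mean. The labels also do not say whether replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

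Each array carried probes for 1881 mouse miRNAs, of which 275 to 574 were detected. The summed miRNA signal averaged 31273 ± 6288 (SD, n = 3) in unsorted control EVs and 98490 ± 8311 in unsorted Abcg2 EVs. By geometric means the Abcg2 arrays were 3.18-fold brighter (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). The mean number of detected miRNAs was 434 ± 33.5 in the controls and 561 ± 18.1 in the Abcg2 arrays, a difference of 126 (exact permutation, two-sided p = 0.1). In the cKit+ fraction the direction was the opposite: summed signal averaged 56229 ± 3744 in controls and 6902 ± 4415 in Abcg2 EVs, where single arrays ranged from 3658 to 11929. The cKit+ Abcg2 arrays were 9.25-fold dimmer (exact permutation, two-sided p = 0.1) and detected 326 ± 70.9 miRNAs against 448 ± 1.15. In NHD13, transgenic arrays were 1.28-fold brighter than wild type (exact permutation, two-sided p = 0.486; 4 against 4 allows 0.0286), but the sets differed: mean summed signal went from 32253 to 74773 in set A and from 60871 to 46120 in set B (n = 2 each). Across miRNAs, which are not independent replicates, Pearson's r between replicates was 0.863 to 0.930 for Abcg2 cKit+ and at least 0.952 in every other group. The 10 brightest miRNAs took 53.8% to 76.8% of the signal, as group means.

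**Figure D1:**
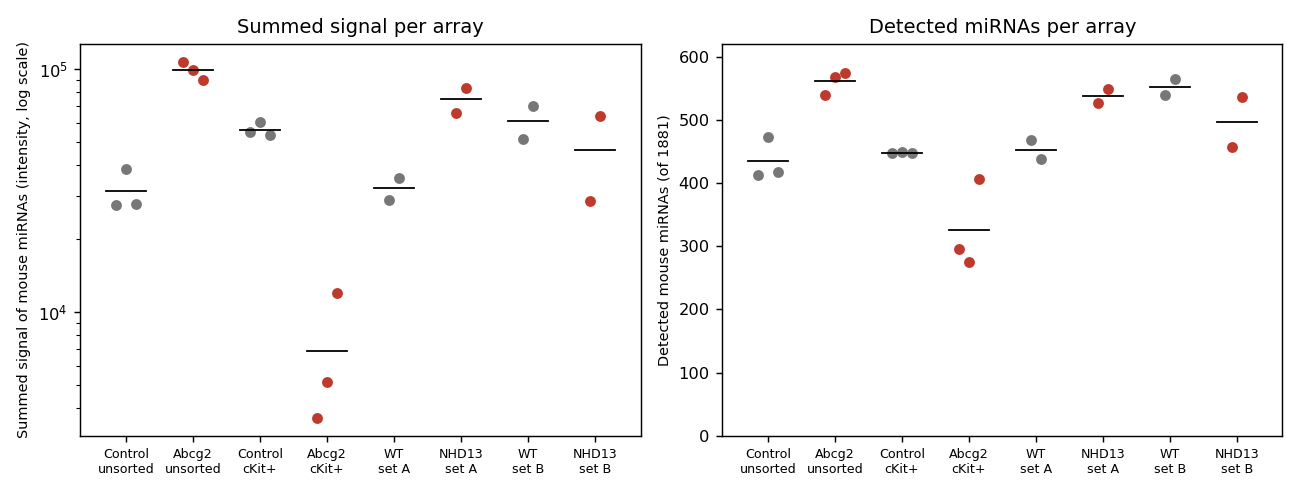
Summed miRNA signal per array on a log axis (left) and number of the 1881 mouse miRNAs detected (right), with each array as a point and each group mean as a horizontal line. The 3 Abcg2 unsorted arrays lay above their controls, and the 3 Abcg2 cKit+ arrays lay below theirs, at 3658 to 11929.

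Each comparison lay on 1 slide. In both Abcg2 comparisons each genotype filled its own line of array positions, so position and genotype cannot be told apart there. In NHD13 the line of positions followed the set. Within each line, wild type filled columns 1 and 2 and transgenic columns 3 and 4. Position and genotype therefore cannot be told apart in NHD13 either. The unsorted arrays, the cKit+ arrays and the NHD13 arrays were on separate slides, so cKit+ and unsorted EVs were not tested against each other directly. All changes below are relative to each array's scaling signal, the 75th percentile over miRNAs detected on every array of the fit, and were tested with limma.

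EVs from unsorted Abcg2 marrow held far less of several miRNAs typical of maturing blood cells. The erythroid miR-451a fell by 7.30 ± 0.44 (SE, n = 3 per group) on the log2 scale, to a 158-fold lower level, and was detected on 2 of the 3 Abcg2 arrays (limma adjusted p = 1.3e-06). Its cluster partner miR-144-3p was at least 22.8-fold lower and was detected on no Abcg2 array. The granulocyte and monocyte miRNA miR-223-3p fell by 5.90 ± 0.36, from a log2 scaled signal of 3.37 ± 0.43 (SD) to -2.53 ± 0.70, a 59.9-fold lower level (adjusted p = 1.3e-06). miR-150-5p, abundant in mature lymphocytes, was at least 60-fold lower (adjusted p = 4.3e-07), and miR-148a-3p was at least 45.3-fold lower. Among miRNAs that gained, miR-3057-5p was at least 56.1-fold higher (adjusted p = 4.3e-07) and miR-6934-5p at least 39.2-fold higher, both undetected in all controls. miR-2137, detected on all 6 arrays, rose by 3.26 ± 0.24, from 1.47 ± 0.15 to 4.73 ± 0.35. For each of these miRNAs, all 3 Abcg2 arrays lay beyond all 3 control arrays. miR-2137 is a member of the list of GC-rich miRNAs of late registry entry, kept as a sign of RNA quality or cross-hybridization.

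In mouse build mm9, as the array files give probe positions, miR-451a lies on chromosome 11 from 77886689 to 77886709 and miR-144-3p beside it from 77886550 to 77886568. The miR-223-3p probe maps to chromosome X from 93438225 to 93438244, and the miR-150-5p probe to chromosome 7 from 52377139 to 52377153. The miR-148a-3p probe maps to chromosome 6 from 51219874 to 51219892.

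Of 533 miRNAs tested in unsorted EVs, 176 rose and 192 fell. Of these 368, 123 differed by more than 4-fold, and 73 were detected on no array of 1 arm. Other large falls were those of miR-1983, by 4.44 ± 0.34, and of the hypoxia-induced miR-210-3p, by 4.20 ± 0.83 (1 of 3 Abcg2 arrays detected). miR-146b-5p was at least 19.6-fold lower and the Hox-cluster miR-10a-5p at least 13.1-fold lower. On the higher side, miR-6963-5p was at least 24.0-fold, miR-339-3p at least 23.1-fold, miR-6935-5p at least 15.0-fold, miR-7069-5p at least 14.7-fold, miR-3077-5p at least 14.0-fold, miR-7066-5p at least 13.7-fold and miR-7051-5p at least 11.2-fold higher. miR-6349 rose by 4.56 ± 0.27 and was detected on 1 control array. miR-21a-5p fell by 1.84 ± 0.40 (adjusted p = 0.0030) and miR-155-5p by 0.96 ± 0.21 (adjusted p = 0.0031), with 3 of 3 Abcg2 arrays below all controls in both cases. miR-146a-5p (0.18 ± 0.37, adjusted p = 0.69) and miR-126a-3p (-0.02 ± 0.38) did not pass. Calls at the largest sizes rest on few arrays, and the counts move with scaling. With the percentile over all miRNAs the split was 187 higher and 113 lower, and the median of all tested miRNAs moved up by 0.23. With normexp background correction it was 82 higher and 364 lower, and miR-339-3p, miR-6935-5p, miR-3077-5p, miR-7066-5p, miR-7051-5p, miR-7069-5p and miR-714 were at -0.12 to -0.43, negative but above the median of all tested miRNAs, which moved to -0.48. With log2 scaling signal as a covariate 16 miRNAs passed.

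Among lists fixed beforehand, all 8 tested let-7 miRNAs, which mark differentiated cells, fell, and all 8 passed adjusted over the list alone. let-7d-5p fell by 4.04 ± 0.40 and let-7g-5p by 3.04, and the median of the list, relative to the median of all tested miRNAs, was -1.98 (camera adjusted p = 0.0047; adjusted p = 0.58 with an estimated correlation). All 3 erythroid miRNAs fell, 3 adjusted over the list alone, with miR-486a-5p at least 7.98-fold lower and a relative median of -4.28 (camera adjusted p = 0.016; adjusted p = 0.58 with an estimated correlation). In the myeloid list 6 of 8 fell, 6 adjusted over the list alone, with miR-142a-3p down from 2.32 ± 0.42 to -0.73 ± 1.12 and a relative median of -1.37 (camera adjusted p = 0.036; adjusted p = 0.58 with an estimated correlation). miR-378a-3p (0.51) and miR-24-3p (-0.52) were the myeloid members that did not pass. All 4 tested members of the cell cycle regulating miR-15 family, which holds miR-16, fell, 4 adjusted over the list alone, led by miR-16-5p, which fell by 2.49, and miR-15b-5p, by 2.43 (camera adjusted p = 0.036; adjusted p = 0.58 with an estimated correlation). GC-rich miRNAs of late registry entry, listed as a sign of RNA quality or cross-hybridization, went the other way: 11 of 16 rose and 2 fell, the same adjusted over the list alone, with miR-714 at least 6.31-fold higher (camera adjusted p = 0.026; adjusted p = 0.58 with an estimated correlation). These 5 directions held under every scaling tried. Over all tested miRNAs, the change correlated with probe GC content (Pearson's r = 0.377). Median probe GC content was 62.9% for miRNAs called higher and 53.2% for those called lower. With each array corrected for its trend on GC content the GC-rich call was lost, its median going from 1.32 to 0.13, and so were the myeloid and miR-15 family calls, with medians going from -1.60 to -1.23 and from -2.21 to -1.64. The latter pair was also lost without Control unsorted replicate 3 and without Abcg2 unsorted replicate 1.

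The remaining lists did not pass camera in unsorted EVs. In the stem and progenitor list 4 of 5 fell, among them miR-221-3p by 1.75 and miR-222-3p by 1.68 (adjusted p = 0.0502), and all 3 miR-29 miRNAs fell (adjusted p = 0.059). In the miR-30 family 4 of 5 fell (adjusted p = 0.089), of 4 NF-kB-induced miRNAs 3 fell (adjusted p = 0.10), and of 5 lymphoid miRNAs 2 fell (adjusted p = 0.17). The imprinted Dlk1-Dio3 cluster was mixed, with miR-370-3p up by 2.48 ± 0.25, miR-494-3p and miR-134-5p also higher, and miR-382-5p and miR-539-5p lower (adjusted p = 0.44). The cell cycle promoting miR-17-92 list had 4 of 11 lower and 0 adjusted over the list alone (adjusted p = 0.32), and the Sfmbt2 cluster 4 of 23 lower and 0 adjusted over the list alone (adjusted p = 0.088). fry, which asks only whether members move one way on balance, passed for 11 of the 13 lists, and no camera call in any comparison held with an estimated correlation. In lists too small to test, the Hox-cluster miR-10a-5p, the miR-34 family member miR-34a-5p (-1.17) and both Runx2-targeting miRNAs, miR-23a-3p (-1.36) and miR-30c-5p (-1.49), fell. Of markers of other cell types, the neural miR-128-3p rose by 3.57 and the hepatocyte miR-193a-3p by 2.23 while miR-122-5p fell by 0.74. The stromal miR-145a-5p (0.65), endothelial miR-126a-3p and muscle miR-206-3p (-0.25) did not pass, and 0 epithelial markers were testable.

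EVs from cKit+ Abcg2 cells also held less of 3 blood-lineage miRNAs than cKit+ controls, from lower starting levels. miR-486a-5p, an erythroid miRNA, was at least 4.35-fold lower (n = 3 per group, limma adjusted p = 9.3e-04), and miR-451a was at least 1.53-fold lower (adjusted p = 0.0038), both undetected on all 3 Abcg2 arrays. miR-223-3p fell by 1.75 ± 0.30 (SE), from -0.20 ± 0.27 (SD) to -1.95 ± 0.34, a 3.36-fold lower level (adjusted p = 0.0047). In the other direction, miR-146a-5p, a feedback inhibitor of NF-kB signalling, was undetected in controls and at least 10.5-fold higher in Abcg2 EVs (adjusted p = 0.0014). miR-155-5p, an activator of inflammatory and myeloid growth programs, rose by 1.30 ± 0.24 (adjusted p = 0.0062). All 3 Abcg2 arrays lay beyond all 3 controls for each of these. The Abcg2 arrays were 9.25-fold dimmer, so a fall below detection here gives only a low bound. With normexp background correction, which moved the median of all tested miRNAs from 0.0542 to 0.58, miR-486a-5p (0.36) and miR-451a (0.53) were positive but below that median.

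Of 431 miRNAs tested in cKit+ EVs, 110 rose and 75 fell, 64 of them by more than 4-fold. The highest were miR-7078-5p, up by 3.81 ± 0.62, and miR-1941-5p, up by 3.54 ± 0.67, followed by miR-6994-5p (3.52), miR-7085-5p (3.41) and miR-6405 (3.40), each of these 3 detected on 1 control array. miR-470-5p was at least 10.3-fold higher, and miR-6404 and miR-5110 both rose by 3.34. miR-150-3p rose by 3.30 ± 0.48, from -2.97 ± 0.65 to 0.33 ± 0.73 (adjusted p = 0.0032, 3 of 3 arrays above all controls). Its partner arm miR-150-5p was at the floor and undetected on all cKit+ arrays of both groups. The rise is thus that of 1 arm only, and cross-hybridization of its probe was not tested. Among falls, miR-5103 fell by 4.42 ± 0.74 with 1 Abcg2 array detected, and miR-8117 fell by 2.73 ± 0.38, from 2.19 ± 0.03 to -0.54 ± 0.69. miR-3057-5p was at least 3.81-fold, miR-697 at least 2.59-fold and miR-8097 at least 2.44-fold lower. miR-139-3p fell by 2.85, miR-3113-5p by 2.77, miR-8109 by 2.61 and miR-202-3p by 2.54, with 1 or 2 Abcg2 arrays detected. miR-21a-5p (0.77, adjusted p = 0.16) and miR-142a-3p (0.16) did not pass. In mm9, the miR-146a-5p probe maps to chromosome 11 from 43187908 to 43187925, the miR-486a-5p probe to chromosome 8 from 24253067 to 24253080, and the miR-150-3p probe to chromosome 7 from 52377178 to 52377189. The count of 185 and its split depend strongly on the settings: 49 higher and 116 lower with the percentile over all miRNAs, 60 and 87 with quantile normalization, 339 and 43 with normexp, and 0 with log2 scaling signal as a covariate (limma, 58 at an unadjusted p under 0.05). The percentile over all miRNAs rests on signal near background on all cKit+ arrays. Without Control cKit+ replicate 1, 2 or 3, the count was 95, 74 or 78, and with no filter on dim miRNAs it was 21, or 233 with miRNAs at the floor on all arrays left out.

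No list passed camera in cKit+ EVs among the 8 tested (limma camera, adjusted p of 0.95 for all with an estimated correlation), and fry passed for 1. In the miR-17-92 list 5 of 10 miRNAs rose, and 8 adjusted over the list alone, with miR-92a-3p up by 1.63, miR-106b-5p by 1.59 and miR-20b-5p by 1.49, and a relative median of 1.12 (camera adjusted p = 0.13). Of 3 NF-kB-induced miRNAs 2 rose, with a relative median of 1.24 (adjusted p = 0.13). Both lists kept their direction under every scaling. GC-rich miRNAs had 1 of 16 higher, miR-5130 (2.64), and 4 lower, among them miR-5126 (-1.90), and 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.27). The miR-15 family had 1 of 3 higher, miR-15a-5p (1.11; adjusted p = 0.71), let-7 had 0 of 7 passing and myeloid miRNAs 1 higher, miR-24-3p (1.52), and 1 lower, miR-223-3p (adjusted p = 0.88 each). Relative medians changed sign with quantile normalization for let-7, myeloid and GC-rich miRNAs, for the latter 2 also with the series values and for myeloid miRNAs with total gene signal, and kept their sign for the miR-15 family. The Dlk1-Dio3 cluster had miR-494-3p higher (1.19) and miR-134-5p lower (-1.09) of 4 (adjusted p = 0.88), and the Sfmbt2 cluster had 0 of 19 passing (adjusted p = 0.27), both with relative medians below 0 under every scaling. In lists too small to test, both erythroid miRNAs fell, both lymphoid miRNAs (miR-181b-5p, 1.94, and miR-181d-5p, 1.48) rose, and miR-30e-5p rose by 1.60 while miR-30d-5p (0.67) did not pass. miR-34a-5p (0.96), miR-23a-3p (0.37), the stem-list miR-221-3p (-0.28) and miR-29a-3p (0.29) and the muscle miR-206-3p (0.96) did not pass. No Hox-cluster, stromal, endothelial, epithelial, hepatocyte or neural list member was testable.

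**Figure D2:**
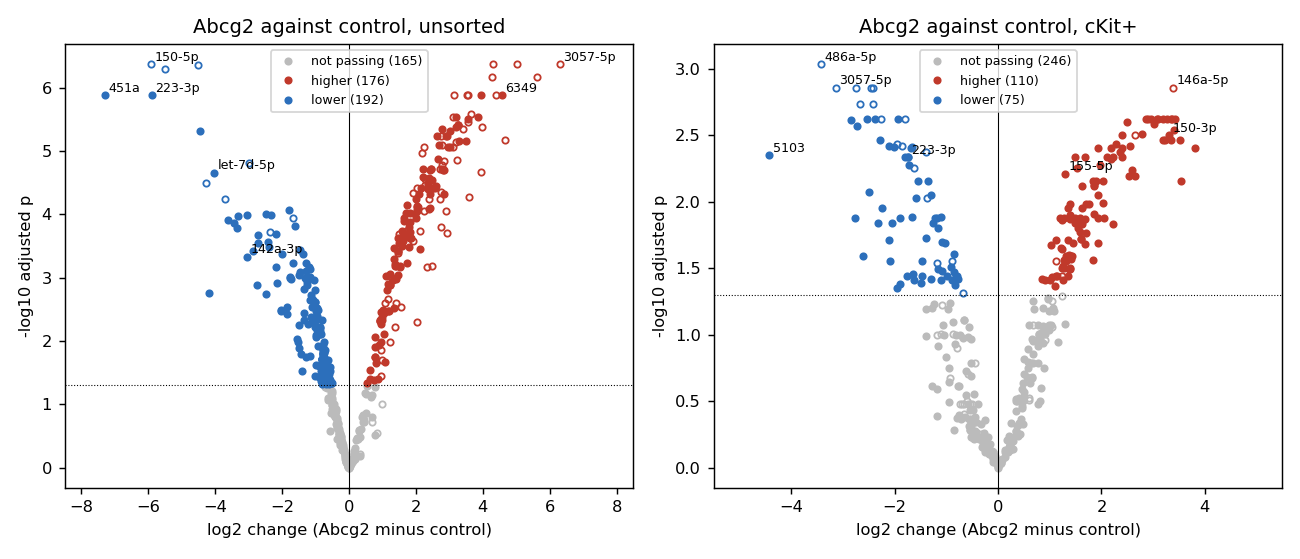
Log2 change (Abcg2 minus control) against -log10 adjusted p from limma for 533 miRNAs in unsorted EVs (left) and 431 in cKit+ EVs (right), with passing miRNAs in red where higher and blue where lower, others in grey, open circles for miRNAs detected on no array of 1 arm, and a dotted line at 0.05. In unsorted EVs 176 rose and 192 fell, and in cKit+ EVs 110 and 75, splits that change to 187 and 113, and to 49 and 116, when arrays are scaled by the percentile over all miRNAs. That percentile rests on signal near background on all cKit+ arrays and on Control unsorted replicates 1 and 3.

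The difference between fractions, each against its own controls, was tested in 1 fit of 12 arrays. miR-339-3p and miR-6935-5p rose in unsorted Abcg2 EVs and had lower values in cKit+ Abcg2 EVs, a difference of at least 4.37 and 4.36 log2 units (limma adjusted p = 1.9e-08 and 2.8e-08), since both were undetected in unsorted controls and in cKit+ Abcg2 EVs. The difference for miR-3057-5p, undetected in the same groups, was at least 7.15 (adjusted p = 5.1e-07): its mean log2 scaled signal went from the floor of -7.75 to -2.30 in unsorted EVs and from -2.96 to -7.08 in cKit+ EVs. For miR-150-5p (adjusted p = 9.1e-08) and miR-144-3p (adjusted p = 9.5e-07), the fitted difference came from the fall in unsorted EVs and has no known size, since both were at the floor in all 6 cKit+ arrays. The same levels place miR-451a at 1.81 in unsorted controls, -5.75 in unsorted Abcg2, -4.33 in cKit+ controls and -6.32 in cKit+ Abcg2 EVs. miR-223-3p went from 2.39 to -3.77 in unsorted and from -0.71 to -2.32 in cKit+ EVs. Of 583 miRNAs tested, 351 differed in their change between fractions, 217 with a higher and 134 with a lower change in cKit+ EVs. Fraction, slide, scan date, Feature Extraction version and brightness difference (3.18-fold brighter against 9.25-fold dimmer Abcg2 arrays) go together here. The split was 113 higher and 196 lower with the percentile over all miRNAs, and 126 and 162 with quantile normalization. With log2 scaling signal as a covariate 20 miRNAs passed, and 128 when only miRNAs detected on all 12 arrays were tested. Over the 351, the covariate took the median size from 2.50 to 1.45 and the median SE from 0.485 to 1.08, and 253 kept their direction. miR-339-3p, miR-6935-5p, miR-150-5p and miR-144-3p still passed at similar fitted values, and miR-3057-5p at -5.09 against -9.57 as fitted without it. With normexp, which moved the median difference of all tested miRNAs from 0.61 to 1.25, those of miR-339-3p (0.98), miR-6935-5p (0.87) and miR-3057-5p (0.47) were positive but below that median.

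**Figure D3:**
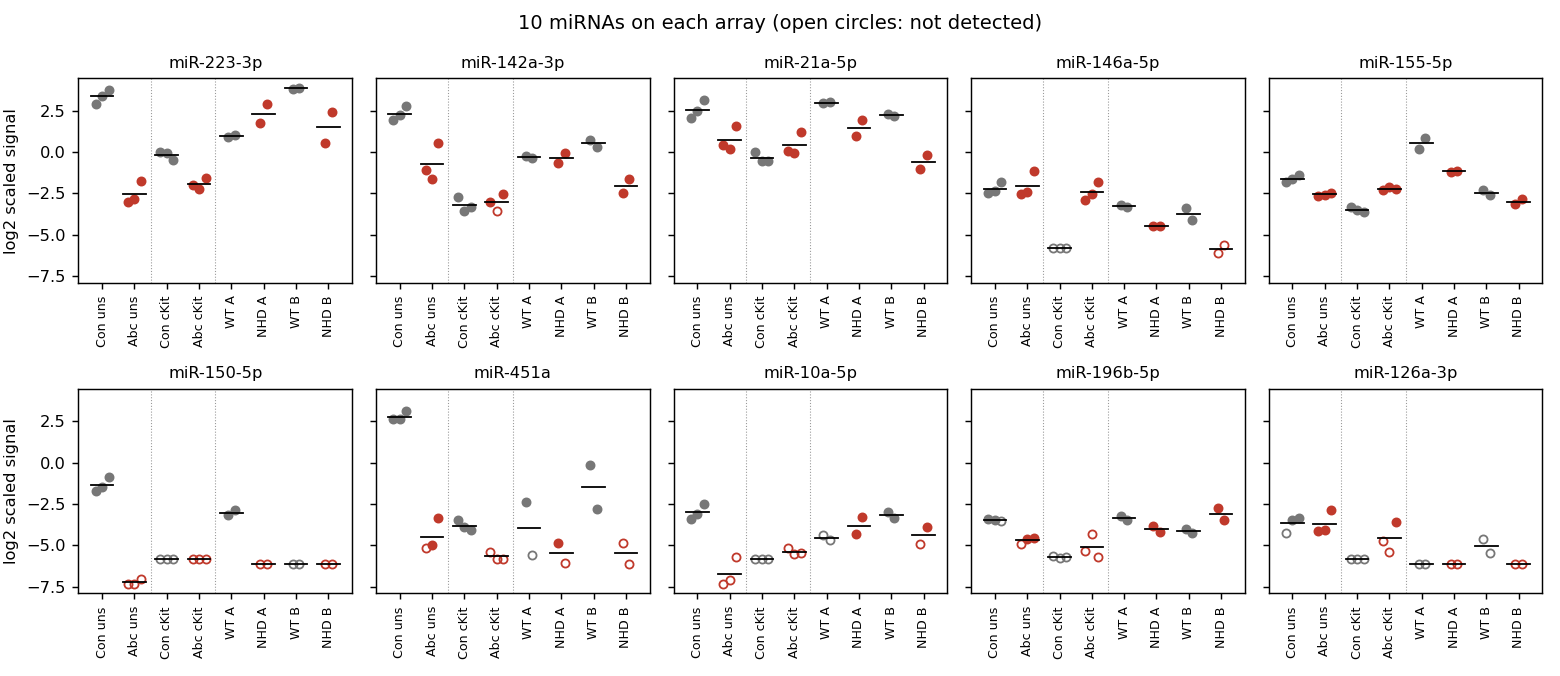
Log2 scaled signal of 10 miRNAs chosen before the data were examined, with 1 point per array, open where the miRNA was not detected, and dotted lines between the 3 fits, which were scaled separately and whose levels are not comparable with each other. miR-451a and miR-223-3p fell by 7.30 and fell by 5.90 in unsorted Abcg2 EVs, and miR-146a-5p was detected in cKit+ Abcg2 EVs but on no cKit+ control array.

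EVs from NHD13 transgenic marrow showed no single miRNA past the threshold against wild type, with the set letter as a term. The closest was miR-21a-5p, an miRNA induced in growth and inflammation, at -2.20 ± 0.41 (SE, n = 4 per group), from 2.62 ± 0.43 (SD) to 0.43 ± 1.29, with 4 of 4 transgenic arrays below all wild-type arrays (limma adjusted p = 0.073). miR-146a-5p (-1.66 ± 0.35), miR-221-3p (-1.23 ± 0.31), miR-342-3p (-2.85 ± 0.73) and miR-23b-3p (-1.94 ± 0.39) had the same adjusted p and also lay lower on 4 of 4 arrays. miR-196b-5p, a Hox-cluster miRNA, differed by 0.20 ± 0.42 and miR-223-3p by -0.52 ± 0.78 (adjusted p = 0.70). The miR-21a-5p probe maps to chromosome 11 from 86397588 to 86397607 in mm9.

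Of 590 miRNAs tested in NHD13, limma called 0, and 144 had an unadjusted p under 0.05, 14 with a higher and 130 with a lower mean in transgenic EVs. miR-351-3p and miR-7672-5p, detected on no transgenic array, had means at least 4.46-fold and 4.14-fold lower, and miR-3963 differed by -2.65 ± 0.53, all 3 also at an adjusted p of 0.073. miR-451a differed by -2.75 ± 0.93 (adjusted p = 0.12) and miR-155-5p by -1.11. miR-150-5p was detected on 2 of 4 wild-type and 0 of 4 transgenic arrays. On the higher side, miR-6908-3p (1.44 ± 0.47, adjusted p = 0.11, 3 of 4 arrays above all wild type), miR-3089-3p (1.30), miR-143-5p (1.20), miR-5134-5p (1.07) and miR-32-3p (0.95 ± 0.37) did not pass. Without WT B1 replicate 3, 72 miRNAs passed, all lower, and without any other single array none did. With log2 scaling signal as a covariate 54 passed, all lower, with normexp 13, and with all 20 arrays in 1 fit 177.

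Of 14 lists tested in NHD13, 5 passed camera although 0 of their members passed alone. The Sfmbt2 cluster, a large rodent imprinted miRNA cluster, had 23 of 24 members with a higher mean and a median of 0.93 relative to all tested miRNAs, led by miR-669n (0.88) and miR-669e-5p (0.80), with 0 adjusted over the list alone (camera adjusted p = 2.1e-07; adjusted p = 0.58 with an estimated correlation). All 8 myeloid miRNAs had lower means, 1 adjusted over the list alone, with a relative median of -0.99 (camera adjusted p = 0.037; adjusted p = 0.58 with an estimated correlation). Stem and progenitor miRNAs (5 tested, 4 lower adjusted over the list alone) and NF-kB-induced miRNAs (4 tested, 3 lower adjusted over the list alone) had relative medians of -0.97 and -1.13 (camera adjusted p = 0.037 each; adjusted p = 0.46 with an estimated correlation). The miR-15 family had 4 of 4 lower adjusted over the list alone, among them miR-322-5p (-1.16) and miR-15a-5p (-0.96), with a relative median of -0.70 (camera adjusted p = 0.037; adjusted p = 0.58 with an estimated correlation). These 5 directions held under every scaling, which moved the median of all miRNAs by up to 0.45, but all except the Sfmbt2 call were lost without WT B1 replicate 3 or without Tg B2 replicate 2. The myeloid, stem and miR-15 family calls were also lost without WT B1 replicate 2 or Tg B2 replicate 3, and the stem, NF-kB and miR-15 family calls without WT A1 replicate 2. The miR-15 family call was lost with the percentile over all miRNAs. The let-7, miR-29, miR-30 and Runx2-targeting lists each had an adjusted p of 0.13 with lower medians, and the lymphoid list 0.21. The Dlk1-Dio3 (0.52), Hox-cluster (0.59), GC-rich (0.64) and miR-17-92 (0.80) lists had larger adjusted p. fry passed for 3 lists, the stem, NF-kB and miR-15 family lists, and not for the Sfmbt2 cluster (adjusted p = 0.21). Of lists too small to test, miR-34a-5p (-0.24), the hepatocyte miR-122-5p (0.33), the neural miR-128-3p (-0.79) and the muscle miR-206-3p (0.47) did not pass.

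The genotype difference was not the same in sets A and B. In set A, 5 of 11 miR-17-92 miRNAs were higher in transgenic EVs, among them miR-19a-3p, which rose by 2.19 ± 0.50 (SE, n = 2 per group, limma adjusted p = 0.0086). In set B miR-19a-3p fell by 3.28 ± 0.50 (adjusted p = 0.0063), and the difference between sets was -5.47 ± 0.70 (adjusted p = 0.0010). The myeloid miR-142a-3p fell by 2.59 ± 0.44 in set B (adjusted p = 0.0068) and differed by -0.06 in set A. miR-223-3p fell by 2.37 ± 0.58 in set B (adjusted p = 0.018) and differed by 1.32 in set A, which did not pass (adjusted p = 0.098). miR-21a-5p fell in both sets, by 1.54 ± 0.45 in A (adjusted p = 0.025) and by 2.85 ± 0.45 in B (adjusted p = 0.0063), and so did miR-146a-5p, by 1.20 in A and to a level at least 4.32-fold lower in B. Each transgenic array lay beyond both wild-type arrays of its set for all of these that passed.

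In set A, 64 miRNAs rose and 131 fell. miR-150-5p was at least 8.40-fold lower (adjusted p = 3.9e-04, 2 of 2 arrays), miR-155-5p fell by 1.69 and miR-342-3p by 4.34, while miR-494-3p rose by 3.93 ± 0.46 and miR-7042-5p by 3.41 ± 0.43. In set B, 91 rose and 119 fell, miR-451a was at least 16.2-fold lower (adjusted p = 0.020, 2 of 2 arrays), miR-340-5p was at least 10.4-fold lower, and miR-150-5p was undetected in both genotypes. The fold for miR-451a is taken from the mean of wild-type arrays that lay far apart, at -0.15 (replicate 2) and -2.82 (replicate 3). It therefore rests largely on replicate 2. Of 590 miRNAs, 251 differed between sets, 136 with a higher and 115 with a lower change in set B. The smallest p-values belonged to miR-7042-5p (-5.75 ± 0.61, adjusted p = 8.4e-04), miR-7051-5p (at least 4.74 lower, adjusted p = 9.6e-04), miR-340-5p (at least 4.90 lower, adjusted p = 9.6e-04), both undetected in set A wild type, miR-494-3p (-5.19 ± 0.65, adjusted p = 0.0010) and miR-19a-3p. The miR-19a-3p probe maps to chromosome 14 from 115443273 to 115443292 and the miR-494-3p probe to chromosome 12 from 110953585 to 110953598 in mm9. Log2 scaling signal differed by 1.16 between genotypes in set A and by -0.27 in set B. The split depended on scaling: with the percentile over all miRNAs it was 118 higher and 50 lower in set A, 100 and 71 in set B, and 69 and 148 for the difference, and with quantile normalization 78 and 51, 99 and 74, and 79 and 124. With 2 arrays per group, single arrays moved the counts: set A gave 45 without WT A1 replicate 2, 75 without WT A1 replicate 3, 30 without Tg A2 replicate 2 and 55 without Tg A2 replicate 3. Set B gave 0 without WT B1 replicate 2 and 0 without Tg B2 replicate 2 (limma, 133 and 118 at an unadjusted p under 0.05), 61 without WT B1 replicate 3, 70 and 67 without Tg A2 replicates 2 and 3, and 120 and 136 without WT A1 replicates 2 and 3. The difference gave 52 without WT A1 replicate 2, 81 and 77 without WT B1 replicates 2 and 3, 53 without Tg A2 replicate 3 and 45 without Tg B2 replicate 2. With log2 scaling signal as a covariate 0 miRNAs passed for set A and 0 for the difference (limma, 64 and 54 at an unadjusted p under 0.05), and 32 for set B. With normexp miR-340-5p was at -0.42 in set A, above the median of all tested miRNAs (-0.47), and at 0.28 for the difference, below its median (0.57), and in set B miR-146a-5p (0.04) and miR-7051-5p (0.05) were positive but below the median (0.08).

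By list, set A had 5 of 11 miR-17-92 miRNAs higher, 5 adjusted over the list alone, with miR-19b-3p up by 2.10 and miR-18a-5p by 1.90 and a relative median of 1.33 (camera adjusted p = 0.0031; adjusted p = 0.97 with an estimated correlation). Set B had 10 lower and 1 higher, miR-18b-5p (1.58), the same adjusted over the list alone, with a relative median of -1.70 (camera adjusted p = 4.1e-04; adjusted p = 0.45 with an estimated correlation). For the difference 8 of 11 were lower, 9 adjusted over the list alone, with a relative median of -3.47 (camera adjusted p = 4.9e-05; adjusted p = 0.74 with an estimated correlation). In set A let-7 had 3 of 7 lower, 4 adjusted over the list alone (camera adjusted p = 0.075), and the median of the myeloid list was -0.16 while its camera direction was up. In set B 7 of 8 myeloid miRNAs fell, 8 adjusted over the list alone, with miR-142a-5p down by 3.37 and miR-27a-3p by 2.94 (camera adjusted p = 2.8e-04; adjusted p = 0.45 with an estimated correlation). The Sfmbt2 cluster had 8 of 24 higher and 1 lower in set B, 11 and 1 adjusted over the list alone, with miR-466l-5p up by 2.21 and miR-669g by 1.90 (camera adjusted p = 5.1e-06; adjusted p = 0.45 with an estimated correlation). All 5 miR-30 miRNAs fell in set B, miR-30e-5p by 2.91 (camera adjusted p = 0.0049), as did all 3 miR-29 miRNAs (adjusted p = 0.028), 3 of 4 NF-kB-induced (adjusted p = 0.028) and all 3 Runx2-targeting miRNAs (adjusted p = 0.043), each with an adjusted p of 0.45 with an estimated correlation. The difference between sets also passed for the myeloid list, 5 of 8 lower and 6 adjusted over the list alone (camera adjusted p = 0.0031), and for miR-30, 3 of 5 lower and 5 adjusted over the list alone (adjusted p = 0.018), both with an adjusted p of 0.74 with an estimated correlation. Relative to all tested miRNAs, the directions of these 7 lists held under every scaling in set B, as did miR-17-92 in set A and all 3 differences, but normexp left relative medians of only -0.059 for NF-kB and -0.071 for Runx2 in set B and -0.17 for the miR-30 difference. Without WT B1 replicate 3 the set B calls of miR-29, miR-30, NF-kB and Runx2 were lost. Those of miR-29, NF-kB and Runx2 were also lost with total gene signal and without WT A1 replicate 3, and those of miR-29 and Runx2 without WT A1 replicate 2. fry passed for 3 lists in set A, 8 in set B and 2 for the difference. Among markers of other cell types in set B, the hepatocyte miR-122-5p rose by 1.77 and the neural miR-128-3p fell by 1.43.

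**Figure D4:**
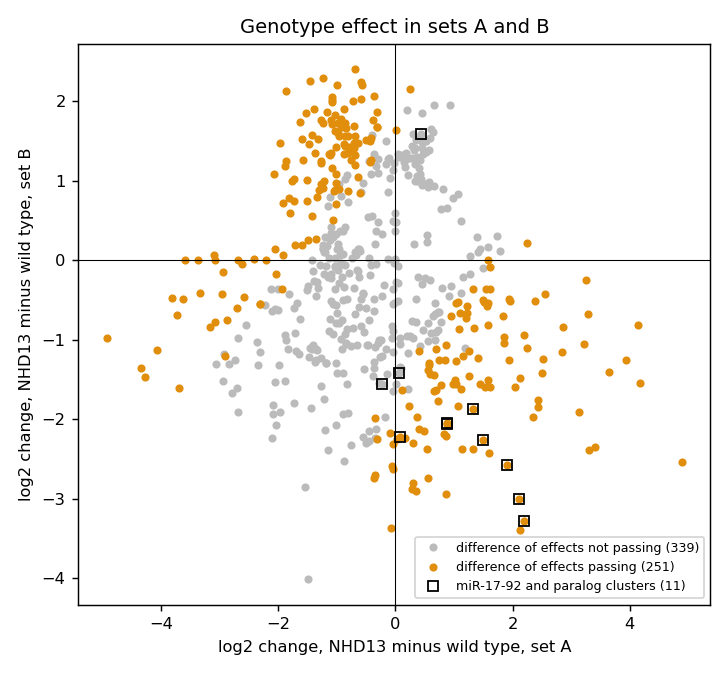
Log2 change (transgenic minus wild type) in set A on the x axis against set B on the y axis for 590 miRNAs, in orange where the difference between sets passed (251) and grey where it did not (339), with squares for 11 members of miR-17-92 and its paralog clusters. Most squares lie right of 0 and below 0, with relative medians of 1.33 in set A and -1.70 in set B, directions that held under every scaling tried.

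Whether the models and fractions moved the same miRNAs was asked by correlating log2 changes across miRNAs, which are not independent replicates; no control array is shared between the 3 comparisons. Changes in unsorted and cKit+ Abcg2 EVs had a weak negative correlation (Pearson's r = -0.27, Spearman's rho = -0.31, 381 miRNAs). Of these miRNAs, 49 rose in unsorted and fell in cKit+ EVs, where independent lists would share 28.2, and 26 rose in both against 33.2. Another 10 fell in both against 18.6, and 22 fell in unsorted and rose in cKit+ EVs against 21.8. The correlation was -0.18 without Abcg2 cKit+ replicate 5, -0.16 with total gene signal and -0.09 with the authors' deposited series values. Changes in unsorted Abcg2 EVs and in NHD13 correlated at r = 0.27 (rho = 0.15, 495 miRNAs), a value that was 0.0758 without WT A1 replicate 2, 0.116 without Tg A2 replicate 3, 0.409 without WT B1 replicate 2 and 0.419 without Tg B2 replicate 2. By set, it was 0.53 for set A and -0.20 for set B. Changes in cKit+ Abcg2 EVs and in NHD13 correlated at r = -0.49 (rho = -0.49, 421 miRNAs), with -0.58 for set A and 0.00069 for set B.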

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

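Chosen after the result was seen were the tests of exchanged genotype labels and of the scaling percentile, the GC content correction and the fit with log2 scaling signal as a covariate. Bootstrap intervals here and in the later sections resampled miRNAs, which are not independent replicates. They do not measure the spread between arrays.

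The genotype effect differed between NHD13 sets A and B, by a test of the difference itself, for 251 miRNAs, led by miR-7042-5p (-5.75), miR-7051-5p (-5.06), miR-340-5p (-5.53), miR-494-3p (-5.19) and miR-19a-3p (-5.47), as fitted, where miR-7051-5p and miR-340-5p had groups at the floor and are known only as at least 4.74 and 4.90. Genotype labels exchanged in 1 set would make the effects mirror each other across all miRNAs, but Pearson's r between them was -0.163 (95% bootstrap interval -0.232 to -0.0940). After the GC content correction 290 miRNAs still differed. These values argue against both as the whole cause. With labels exchanged in 1 set, the fit with the set letter called 68 miRNAs against 0 as labelled, but any difference between sets could also give this. Array brightness stays open: the difference followed each miRNA's slope on log2 scaling signal within groups (r = -0.663, interval -0.714 to -0.605), so brightness may contribute, and its source was not tested. With that signal as a covariate 0 miRNAs passed (limma, 54 at an unadjusted p under 0.05), but mostly because the spread widened: over the 251 the median size went from 2.52 to 1.97 and the median SE from 0.654 to 1.06, and miR-7042-5p went from -5.75 ± 0.61 to -4.94 ± 0.97. A difference between the mice or cells behind the letters also stays open, untested, and the line of array positions cannot be told apart from the set.

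The Abcg2 effect differed between the unsorted and cKit+ fractions, by a test of the difference itself, for 351 miRNAs, led by miR-339-3p (-7.41), miR-6935-5p (-7.41), miR-150-5p (5.42), miR-3057-5p (-9.57) and miR-144-3p (3.92). These are fitted values with undetected groups at the floor, not sizes: the bounds are at least 4.37, 4.36 and 7.15 for miR-339-3p, miR-6935-5p and miR-3057-5p, and the other 2 have none. In 100 regroupings drawn within fractions, the real one alone, 1, gave as many, with 200 the highest of the others. The regroupings mix Abcg2 and control arrays, so they also remove the Abcg2 effect within each fraction. They therefore cannot tell a difference between the effects from the effects themselves, and chance stays open for the difference. For the dim Abcg2 cKit+ arrays, the choice of scaling percentile stays open. The percentile over all miRNAs moved the median change from 0.0542 to -0.55, and 49 of the 110 miRNAs called higher kept their call with it. The 75 of 75 called lower that did were bound to by that shift. On every cKit+ array fewer miRNAs were detected than lie above this percentile, so it rests on signal near background. Lost calls may come from that, and the setting cannot decide the question. Brightness stays open too: the cKit+ effect followed the slope on log2 scaling signal (r = -0.533, interval -0.595 to -0.468), so part of it may go with array brightness. The labels give 100 ng of labelled RNA for every array, and what made these arrays dim was not tested. A difference between progenitor and whole marrow EVs in their response to the disease stays open, untested apart from slide, scan date, Feature Extraction version and brightness.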

How the results depend on the processing

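Chosen after the result was seen were normexp on the median signal, the GC content correction, log2 scaling signal as a covariate, the crossed block, the fits without constant miRNAs, the cKit+ fit without its dimmest arrays and the correlations without single arrays.

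Counts and correlations stayed within 1.5 times the original value (correlations within the spread of leaving out arrays) in 137 recomputations and moved further in 66. Of recomputed values of named miRNAs, 3627 kept their side of the threshold, 289 fell short of it, 129 newly passed and 39 changed sign, and for lists 801, 37, 44 and 0. A change of sign was counted only where the miRNA or list passed before or after, and for lists by the camera direction. List medians that changed sign without a call, as for let-7 and myeloid miRNAs in cKit+ EVs, are therefore not among them. Calls that held under every alternative run were 5 of 50 named miRNAs in unsorted EVs (miR-3057-5p, miR-150-5p, miR-148a-3p, miR-144-3p and miR-370-3p). All of these except miR-370-3p were detected on no array of 1 arm. They were therefore not run in the fit of miRNAs detected on every array, and only a bound on their change is known. For the fractions 2 of 5 held (miR-150-5p and miR-144-3p). Both were at the floor on all cKit+ arrays in the main fit, so these calls rest on the fall in unsorted EVs. In cKit+ EVs 0 of 31 held, in each NHD13 set 0 of 9, and for the difference of sets 0 of 5. List tests were rerun under fewer settings: quantile normalization, the percentile over all miRNAs, total gene signal, the GC content correction and leaving out each array. List calls that held under all of these were let-7 and erythroid in unsorted EVs, Sfmbt2 in NHD13 and miR-17-92 in set A. In set B they were miR-17-92, myeloid and Sfmbt2, and for the difference of sets all 3. All of these used the preset correlation. With an estimated correlation no list call held in any comparison (camera, smallest adjusted p = 0.45). Signal over background limits what can be said of Abcg2 cKit+ EVs, with 275 to 407 miRNAs detected, and of miRNAs detected in 1 arm, where only a bound is known. Where no cause is named below, the cause was not tested.

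With log2 scaling signal as a covariate, which widens the spread where groups differ in brightness (median SE of called miRNAs from 0.245 to 0.914 in unsorted EVs, their median size from 1.38 to 1.28, and for cKit+ from 0.359 to 0.681 and from 1.68 to 1.11), the counts were 16 (unsorted), 0 (cKit+; limma, 58 at an unadjusted p under 0.05), 54 (NHD13), 0 (set A; 64), 32 (set B), 0 (difference of sets; 54) and 20 (difference of fractions). With normexp on the median signal they were 382 for cKit+, 13 for NHD13, 359 for set A, 114 for set B and 542 for the fractions. With no filter on dim miRNAs they were 21 for cKit+, 1213 for set A, 1137 for set B and 6 for the difference of sets, but these fits are distorted by miRNAs at the floor on all arrays: 967 of the calls in each set are such miRNAs, passing by rounding error. With no filter and these constant miRNAs left out the counts were 603 for unsorted, 84 for set B and 599 for the fractions, and the others, 233 for cKit+ among them, stayed within 1.5 times. Each main fit held 1 such miRNA, not called, and without it the counts were 367 (unsorted), 183 (cKit+), 0 (NHD13, smallest adjusted p = 0.063), 196 (set A), 257 (set B), 265 (difference of sets) and 351 (fractions). With only miRNAs detected on every array, which leaves fewer to test, 3 passed for NHD13, 165 for the difference of sets and 128 for the fractions. Total gene signal gave 1 for NHD13 and 133 for set B, and the series values gave 2 for NHD13, 108 for set A, 71 for set B and 136 for the difference of sets. Quantile normalization gave 129 for set A. All 20 arrays in 1 fit, which share 1 spread, gave 308 for cKit+ and 177 for NHD13. Leaving out the 2 dimmest Abcg2 cKit+ arrays, replicates 4 and 5, left 1 Abcg2 array, so no count is given for that fit.

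Leaving out each array in turn gave 74 to 225 for cKit+, 0 to 72 for NHD13, 30 to 170 for set A, 0 to 142 for set B and 45 to 245 for the difference of sets, and the unsorted and fraction counts stayed within 1.5 times. Where that left 1 array in a group, it was assumed to vary like the others. The correlation of unsorted with cKit+ changes was -0.217 with quantile normalization, -0.161 with total gene signal, -0.0905 with the series values, and -0.314 to -0.181 without single arrays. That of unsorted with NHD13 changes was 0.0758 to 0.419 and that of cKit+ with NHD13 changes -0.577 to -0.381 without single arrays.

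Where a value passed before or after, signs changed as follows, in log2 units. Normexp shrank large changes (miR-339-3p in unsorted EVs from 5.02, miR-486a-5p in cKit+ EVs from -3.43) and moved the median of all tested miRNAs, to -0.48 in unsorted EVs, 0.58 in cKit+ EVs, -0.47 in set A, 0.08 in set B, 0.57 for the difference of sets and 1.25 for the fractions. Of the miRNAs listed here, only miR-539-5p and miR-466p-5p in cKit+ EVs crossed that median under it, though many came near it, while all sign changes under the GC content correction and the covariate remained relative to the median. In unsorted EVs with normexp on the mean signal, miR-339-3p was -0.12, miR-6935-5p -0.28, miR-3077-5p -0.35, miR-7066-5p -0.36, miR-7051-5p -0.40, miR-7069-5p -0.28, miR-181b-5p -0.39, miR-146a-5p -0.34 and miR-714 -0.43. With the GC content correction miR-539-5p was 0.37 and miR-669g 0.54, and with the covariate miR-342-3p was 0.48, miR-322-5p 0.12, miR-30c-5p 0.23 and miR-30d-5p 0.37. In cKit+ EVs with normexp on the median signal, miR-486a-5p was 0.36, miR-3057-5p 0.40, miR-139-3p 0.28, miR-3113-5p 0.39 (0.71 with the covariate), miR-697 0.51, miR-8097 0.52, miR-8109 0.11, miR-202-3p 0.0169, let-7d-5p 0.55, miR-16-5p 0.42, miR-134-5p 0.25, miR-370-3p 0.34, miR-539-5p 0.61, miR-467e-5p 0.56, miR-466p-5p 0.58 and miR-451a 0.53. With the same correction, miR-340-5p was -0.42 in set A and 0.28 for the difference of sets, and in set B miR-146a-5p was 0.0381 and miR-7051-5p 0.0494. For the fractions miR-339-3p was 0.98, miR-6935-5p 0.87 and miR-3057-5p 0.47.

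With the replicate number as a block, 359 miRNAs passed in unsorted EVs, 0 in NHD13 (limma, 98 at an unadjusted p under 0.05), 252 in set A and 312 in set B, and 306 in set B with crossed numbers. Deviations of equal numbers correlated at -0.231, 0.113 and 0.103 in unsorted EVs, 0.443 in set A and -0.150 in set B, so the numbers were not taken to pair samples, and not every array correlated best with its own number. For cKit+ EVs alone, no paired analysis was possible because those groups share no replicate numbers. The slide block was not run, since each comparison lay on 1 slide.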

Other observations

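Chosen after the result was seen were the NHD13 split counts, the covariate fit and its splits, the GC content correction, the tests of brightness against correlation sign and of shared control arrays, and the miRNAs singled out in the covariate fit.

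With log2 scaling signal as a covariate, 54 miRNAs were lower in NHD13 transgenic EVs and 0 higher (limma, 234 at an unadjusted p under 0.05). They were led by miR-21a-5p, which fell by 2.60 ± 0.28 (SE, n = 4 per group), followed by miR-26b-5p (-2.21), miR-26a-5p (-1.90), miR-30c-5p (-1.88), miR-142a-5p (-2.55) and miR-29c-3p (-2.19). By list, 7 of 8 myeloid, 4 of 5 stem and progenitor, 3 of 4 NF-kB-induced, 3 of 4 miR-15 family, 3 of 3 miR-29, 4 of 5 miR-30 and 3 of 3 Runx2-targeting miRNAs fell, against 2 of 11 miR-17-92 and 0 of 24 Sfmbt2 miRNAs. Of the 35 splits of the 8 arrays into equal groups, 1, the real one, gave as many, and the highest of the others gave 50, a narrow margin in a fit chosen after the main fit had called 0, so chance stays open for this count.

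Unsorted Abcg2 EVs differed from unsorted controls in the direction in which cKit+ control EVs did (Pearson's r = 0.756, Spearman's rho = 0.749, across 583 miRNAs, which are not independent replicates). For miR-142a-3p the mean log2 scaled signal was 1.34 in unsorted controls, -1.97 in unsorted Abcg2 and -3.72 in cKit+ controls, and for let-7d-5p it was -0.89, -5.19 and -4.43. Both differences use the same unsorted control arrays, and the covariance was 2.98 against 0.0320 in 200 simulations of unchanged groups. The simulations drew independent noise per miRNA from the spread between replicates. They argue against that spread in the shared controls as the whole source. An error common to all unsorted control arrays would enter both differences and was not simulated. In level, unsorted Abcg2 EVs correlated about equally with cKit+ controls (r = 0.790) and with unsorted controls (r = 0.788). Part of the resemblance may still come from the shared controls, and fraction, slide, scan date and Feature Extraction version cannot be told apart here. Unsorted Abcg2 and cKit+ control arrays were also both brighter than unsorted controls, with mean summed signals of 98490 and 56229 against 31273. Brightness therefore stays open too, and the simulations did not address it.

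The 192 miRNAs that fell in unsorted Abcg2 EVs did so on arrays 3.18-fold brighter than controls. Probe GC content is argued against as the whole cause, since 156 of them were still called lower after the GC content correction. Scaling stays open for most, since leaving it out adds about 1.33 to changes of miRNAs above the floor and most falls were smaller: in unscaled processed signal their median change was 0.414 (95% bootstrap interval 0.322 to 0.523), against -0.92 after scaling, so many may have kept or raised their amount while others rose more. Unscaled values were lower for 55 of the 192, and by more than 4-fold for 13, with the 8 that no Abcg2 array detected held at their bound, among them miR-451a (-5.97), miR-223-3p (-4.57) and, as bounds, miR-150-5p (-4.96 or lower), miR-148a-3p (-4.55 or lower) and miR-144-3p (-3.82 or lower), for which the fall did not need the scaling. Over all 533 tested miRNAs, the unsorted change also followed each miRNA's slope on log2 scaling signal within groups (Pearson's r = 0.305, 95% bootstrap interval 0.232 to 0.376). No bound was set for this value beforehand, and brightness stays open as well.

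The sign of the correlation of effects across miRNAs was that of the product of the differences in log2 scaling signal in 6 of 6 pairs among unsorted Abcg2, cKit+ Abcg2 and NHD13 sets A and B, from 0.53 for unsorted Abcg2 with set A, both brighter than their controls, to -0.58 for cKit+ Abcg2 with set A. For cKit+ Abcg2 with set B the correlation was 0.00069. The pairs share comparisons, so they are not independent. In set B the scaling signals of the genotypes overlapped, at 80.7 and 108.9 in wild type and at 57.1 and 105.5 in transgenic arrays. The sign of its brightness difference is therefore uncertain.

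The 6 arrays of each Abcg2 comparison make 10 splits, the real one included, too few for a share under 0.05. In unsorted EVs the real split gave 368 miRNAs, alone (1 split), against 0 in the highest other, and 5 lists, a number that 3 splits reached, against 10 in the highest other. In cKit+ EVs it gave 185 miRNAs (1 split) against 0, and 0 lists, as many or more in all 10 splits, against 3. In NHD13 all 35 splits gave at least the real count of 0 miRNAs (limma), with 68 in the highest other. That split, WT A1 with Tg B2 against WT B1 with Tg A2, is the contrast of the genotype effect between sets. Its count restates the difference between sets given above and is not separate evidence. The 5 lists were reached by 8 of the 35 splits, with 9 the highest other, and the 144 miRNAs at an unadjusted p under 0.05 by 3, with 228 the highest other, so chance cannot be excluded for either.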
